A study of Mus musculus with 5 samples.

How the data were processed

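The samples were RNA of 2 lines of spontaneously immortalised mouse embryo fibroblasts, called MEFF and MEFB. Per the labels, the embryos were taken at 12.5 days after conception and the strain was FVBN. Each line carries the Thp deletion on 1 copy of chromosome 17, on opposite parental copies. The labels place this deletion between the genes T and Sod2, at 8.6 to 13.2 Mb of the mm9 build, and give its length as at least 4.6 Mb. They add that it holds the imprinted Igf2r gene cluster of 400 kb. The 5 2-colour tiling arrays fall into 3 groups by the labels: 2 arrays of MEFF total RNA, 2 of MEFF polyA RNA and 1 of MEFB polyA RNA. In each hybridisation, Cy3 carried double-stranded cDNA and Cy5 carried sonicated genomic DNA (input) of the same line, per the labels. Such cDNA keeps no strand, so transcripts of both strands were read together. Dyes were not swapped, so dye effects shared by all arrays stay in the ratios and cancel only in differences between arrays.

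The deposited values are the raw intensity of each probe in each channel, extracted with NimbleScan 2.2.34, per the file headers. They carry no background subtraction and no normalization between channels or arrays, judging from the values. Labelling and hybridisation were done by the array maker, and the input DNA was amplified with T7 polymerase, per the labels. The array holds 388000 probes, of which 387986 lie on chromosome 17 and 14 elsewhere. The median spacing was 139 bp. Probes at the scanner limit of 65535 numbered between 1 and 81 per channel and array and were kept.

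From these intensities, log2(cDNA/input) was computed per probe and centred on the median of each array. Values were then averaged over windows of 5 kb with at least 8 probes, which gave 15383 windows with a median of 26 probes. No loess or quantile step was used in the main setting, because cDNA set against genomic DNA is not balanced around 0. Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on all 5 arrays with 3 group means. That fit has 2 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all windows, and the threshold was an adjusted p of 0.05. The contrasts were MEFF total RNA minus MEFF polyA RNA and MEFB polyA RNA minus MEFF polyA RNA. In the latter, the lone MEFB array is assumed to vary like the other groups. A window counted as transcribed when its mean, standardised by probe number, passed an empirical false discovery rate of 1% on each array of a group, against 100 shuffles of the probe values over positions. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision throughout.

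The alternatives fixed before the data were examined were the median of probes, windows of 2 and 10 kb, loess within arrays with a span of 0.3, and quantile normalization between arrays. Others were normexp background correction with offset 50, the cDNA channel alone, removal of probes in the lowest 10% of input signal on any array, a trended prior, a fit of the compared groups alone, and each replicate left out. Normexp estimates the background from the low part of each channel, and on a tiling array it takes some signal for background. Changes were made one at a time. Chosen after seeing the data were normexp combined with each left-out replicate, normexp followed by quantile normalization, transcribed windows after normexp, and the deletion interval moved to placed positions. The rule for named regions took, per direction, the 5 longest runs of called windows, with gaps of up to 1 window, and the 5 windows with the largest difference, plus every run inside the deletion interval. The 5 windows were taken from those transcribed in either group compared. As the main setting called 0 and 1 windows, the run rule was applied to the windows called after normexp, a choice also made after seeing the data.

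The genome build of the probe positions is not given in the sources used here. The positions did not match NCBIM37, the build of the reference at hand and the same as mm9. Across probes, the correlation of the input signal with the signal predicted from the base composition of the NCBIM37 sequence was 0.012 at the file positions. The report therefore gives chromosome 17 positions as in the array files, and its comparisons name no gene from an annotation. Genes are named only in the closing section, by the placing described next. The interval of the labels was set at the same numbers in file positions, which can lie off the true place.

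To name candidate genes for the closing section, blocks of 25 kb of probes were placed on NCBIM37 by the input signal alone, with no cDNA value used. Each block was shifted along the sequence until the predicted input signal matched best over 50 bases per probe. A block was accepted at z of at least 5 with a lead of 1.5 over the next shift, or at z of at least 4 within 1000 bp of the shift of an accepted neighbour. The neighbour rule was added after the Igf2r blocks had stayed unplaced under the stricter rule. An earlier version with larger blocks had placed a smaller share of them, and the block size was reduced after seeing that. Of 3387 blocks, 2555 were placed, against 51 with shuffled values, and 78.7% of the chromosome 17 probes lay in them. The stricter rule alone placed 1914, against 2 with shuffled values. The correlation at placed positions was 0.564. As a check on values not used for placing, cDNA signal in annotated exons exceeded that elsewhere by 0.67 to 1.74 (log2) on the 5 arrays, against 0.00531 to 0.0939 at file positions. No position on NCBIM37 is printed. The deletion interval at placed positions ran from the first to the last placed probe within the numbers of the labels. None of the 3029 probes that follow it in the interval's file numbers was placed, so its upper end is not known.

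On placed probes, gene values were means over at least 4 exon probes or, for introns, at least 10 intron probes outside every annotated exon, tested with limma as above. This gave 756 genes with exon values and 609 with intron values. The naming rule took the tested members of the Thp region and Igf2r cluster list, and per direction the 10 genes with the largest difference past the threshold whose arrays did not overlap. As the main setting called 0 genes, the rule was applied after normexp and to genes transcribed in either group, both choices made after seeing the data. Single values of 2 members of that list are not reported here. A gene counted as transcribed when its exon mean passed the threshold of the windows on each array of a group. The 17 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and with an estimated correlation.

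The procedures were tested on simulated data with 200 windows or genes changed by known amounts. For total minus polyA RNA over 15383 windows, changes of 0.5, 1 and 2 (log2) were recovered in 36.4%, 98.5% and 100% of cases in the main setting, and in 13.6%, 79.1% and 100% after normexp. For MEFB minus MEFF, the shares were 4.55%, 89.6% and 100% in the main setting, and 1.52%, 44.8% and 100% after normexp. Unchanged windows called beside these numbered 12 and 19 in the main setting, more than the nominal 5% of calls, and 7 and 5 after normexp. Over 756 genes, changes of 1 were recovered in 68.7% and 35.8% of cases in the main setting and in 43.3% and 19.4% after normexp, with 9, 9, 1 and 5 unchanged genes called. The simulated noise was normal, independent and equal in all groups, and the changed windows were picked at random. In real bright windows the SD between the MEFF polyA arrays reached 1.2. A real difference of -1.9 between total and polyA RNA did not pass as deposited (limma, adjusted p = 0.57). The shares recovered therefore do not describe bright windows. With positions shuffled, 0 windows were called transcribed on each array. The threshold itself came from such shuffles, so this is not a separate test of false calls. Figures and placement used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.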

Results

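Transcription along mouse chromosome 17 was mapped by hybridising double-stranded cDNA against genomic DNA on tiling arrays, in 2 independent lines of embryo fibroblasts. MEFF carries the Thp deletion with the genotype written Thp/+, and MEFB with the genotype +/Thp. The groups were MEFF total RNA (n = 2), MEFF polyA RNA (n = 2) and MEFB polyA RNA (n = 1). Positions are chromosome 17 positions as in the array files, whose genome build is not given in the sources used here. Levels are log2(cDNA/input) means of 5 kb windows, centred on the median of each array.

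The arrays differed in signal over background. The median cDNA intensity was 2560.56 and 2542.22 on the MEFF total RNA arrays, 1568.44 and 568.78 on the MEFF polyA arrays, and 747.22 on the MEFB array. The 99th percentile lay 5.42 and 5.33 times above that median on the total RNA arrays, 9.17 and 22.4 times on the MEFF polyA arrays and 20.7 times on the MEFB array. The SD of the window levels was 0.357 and 0.354 for total RNA, 0.371 and 0.63 for MEFF polyA RNA and 0.575 for MEFB. Over windows, which are not independent replicates, the correlation between replicates was 0.974 for total RNA and 0.952 for polyA RNA. The MEFB array correlated with the MEFF polyA arrays at 0.876 and 0.86. The total RNA and polyA RNA arrays came from different series of slides, so array lot and RNA type cannot be told apart.

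The stated aim of the design was to map expression along the chromosome. Of 15383 windows, 1359 (8.83%) were transcribed in MEFF total RNA, 1080 (7.02%) in MEFF polyA RNA and 1468 (9.54%) in MEFB polyA RNA. Transcription was densest between 20 and 35 Mb. In the bin from 30 to 35 Mb, 20.1% of 814 windows were transcribed in MEFF total RNA, 25.4% in MEFF polyA RNA and 25.1% in MEFB. From 20 to 25 Mb, the shares were 20.3%, 21.5% and 25.2% of 711 windows. The sparsest bin, from 90 to 95 Mb, had 0.403% of 496 windows transcribed in each group. The shares of MEFF total and polyA RNA lay furthest apart from 5 to 10 Mb, at 13.1% against 4.13%, and MEFB had 8.73% there. From 60 to 65 Mb, total RNA had 11.8%, MEFF polyA RNA 4.76% and MEFB 14.5%. These differences between bins were not tested.

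**Figure D1:**
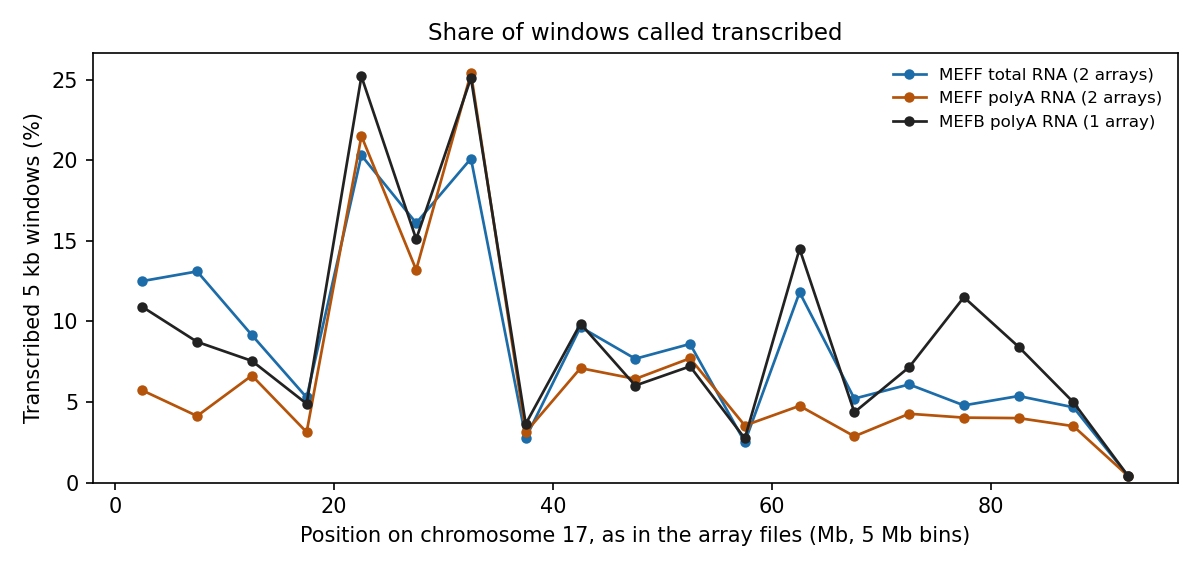
Share of 5 kb windows called transcribed (y axis, %) in bins of 5 Mb along chromosome 17 (x axis, position as in the array files, Mb), 1 line per group. All 3 groups peak between 20 and 35 Mb, and each falls to 0.403% from 90 to 95 Mb.

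A common set of windows was read in all samples. All 3 groups shared 795 transcribed windows, which was 42.4% of the windows transcribed in any group. MEFF total and polyA RNA shared 885, where independent placement would give 95, and MEFF polyA and MEFB shared 940 against 103. Windows called in a single group numbered 265 for MEFF total RNA, 50 for MEFF polyA RNA and 319 for MEFB. A group with 2 arrays needs a call on each of them, so these numbers favour MEFB. On single arrays, 1495 and 1440 windows were called for MEFF total RNA and 1102 and 1509 for MEFF polyA RNA. The longest run of windows transcribed in all 3 groups ran from 34330000 to 34404999 (75 kb), with 13 of its windows called. It was followed by 54890000 to 54954999 (65 kb), 32120000 to 32179999 (60 kb) and 45085000 to 45144999 (60 kb).

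The comparison of MEFF total with MEFF polyA RNA set all RNA of a line beside the part of it with a polyA tail. With intensities as deposited, 0 of 15383 windows passed limma's test (lowest adjusted p = 0.452), and 1189 passed at an unadjusted p of 0.05. After normexp background correction, 518 windows passed, 106 higher and 412 lower in total RNA. After quantile normalization, 929 passed, 389 higher and 540 lower. After loess, 0 passed. The directions below are those of the normexp setting, where the median difference of all windows was -0.103.

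The windows higher in total RNA formed 53 runs, the longest of 65 kb. Between 61480000 and 61544999, the level was 0.422 and 0.38 on the total RNA arrays against 0.103 and 0.154 on the polyA arrays. The difference after normexp was 0.769 (lowest adjusted p = 0.014, limma). The neighbouring run from 61660000 to 61704999 (45 kb) stood at 0.584 and 0.53 against 0.079 and 0.24, a difference of 0.93 after normexp (lowest adjusted p = 0.0027). A run from 61190000 to 61224999 (35 kb) rose by 0.84, and runs of 35 kb at 16240000 to 16274999 and 28615000 to 28649999 rose by 0.897 and 0.788. The window from 28635000 to 28639999 had the largest difference among transcribed windows higher as deposited, 0.983 ± 0.087 (SD, n = 2) in total RNA against 0.409 ± 0.1 (SD, n = 2) in polyA RNA. That difference of 0.574 did not pass as deposited (SE 0.096, adjusted p = 0.57) and was 1.26 after normexp (SE 0.22, adjusted p = 0.0034). Windows starting at 61680000, 61165000, 86630000 and 61665000 differed by 0.561, 0.491, 0.464 and 0.464 as deposited, and passed at 1.28, 1.08, 1.17 and 1.04 after normexp. With normexp and total RNA replicate 1 left out, the window from 28635000 was not called. Those from 61665000 and 61680000 were not both called with either total RNA array left out. Within the deletion interval of the labels, called windows higher in total RNA clustered from 9635000 to 9729999, with runs of 20 kb (1.01) and 30 kb (1.01), and 2 single windows of 1.03 and 1.24. A single window at 12455000 was higher by 0.97, and windows at 9620000, 10505000 and 12830000 had differences of -0.868, -0.927 and -0.906. After quantile normalization alone, a run of 75 kb from 12150000 to 12224999 was also higher in total RNA (1.01).

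**Figure D2:**
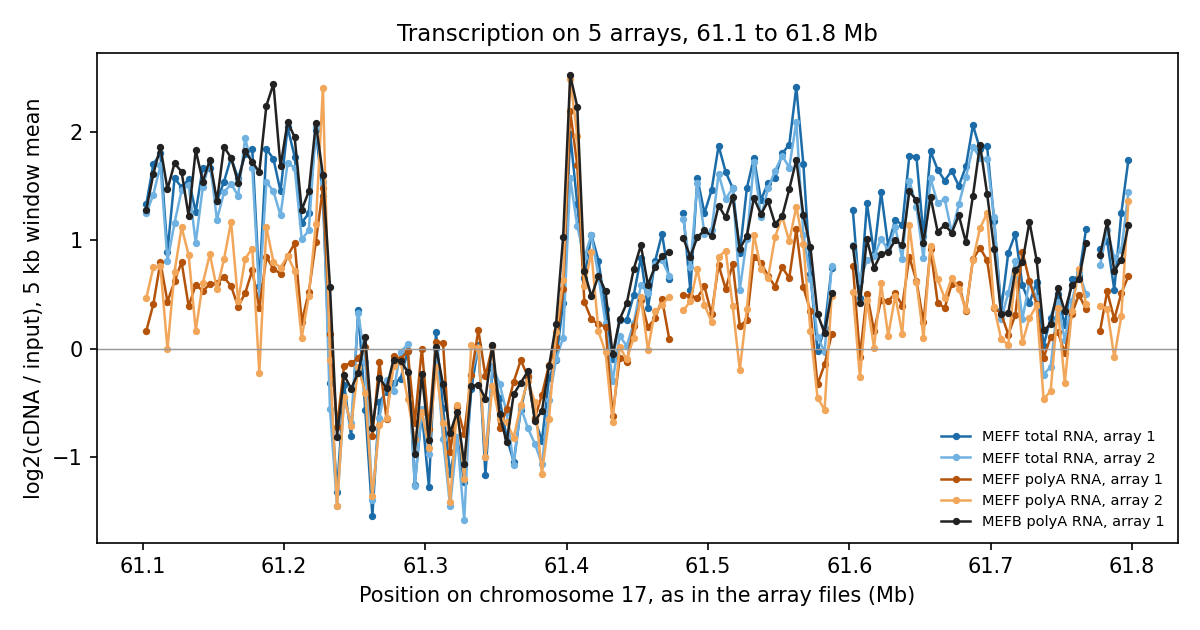
Level of each 5 kb window (y axis, log2(cDNA/input) after normexp) over the part of the chromosome that holds 3 runs higher in total RNA (x axis, position as in the array files, Mb), 1 line per array, with gaps where windows lack probes. Between 61480000 and 61544999 the total RNA arrays averaged 1.39 and 1.24, the MEFF polyA arrays 0.557 and 0.533, and the MEFB array 1.15.

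As deposited, MEFB polyA RNA stood above total RNA in the windows from 28635000 (1.07 against 0.983), 61165000 (0.861 against 0.524) and 61665000 (0.561 against 0.534). It stood below total RNA in those from 61680000 (0.456 against 0.565) and 86630000 (0.579 against 0.873), and above the MEFF polyA mean in all of them. In each of the 5 runs higher in total RNA, MEFB also stood above each MEFF polyA array as deposited. It stood above each total RNA array too, except in the run from 16240000 (0.522 against 0.677 and 0.643). After normexp, it exceeded each total RNA array only in the run from 61190000 (1.85 against 1.63 and 1.46). Low MEFF polyA levels, subtracted in both comparisons, could therefore take part in these differences.

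The windows lower in total RNA formed 240 runs, mostly short, with a median of 5 kb. The longest, from 34355000 to 34414999 (60 kb), lay within one of the densest parts of the chromosome. Its level was 0.824 and 0.811 in total RNA against 1.51 and 2.38 in polyA RNA, and it fell by 1.19 after normexp, with 12 of 12 windows called (lowest adjusted p = 0.0026, limma). Runs of 45 kb at 33470000 to 33514999 and 44800000 to 44844999 fell by 1.05 and 1.26. A run of 40 kb at 30720000 to 30759999 had a mean difference of -0.992, and one of 35 kb at 23160000 to 23194999 fell by 1.32. Among single windows, 27700000 to 27704999 stood at 0.616 ± 0.11 in total RNA and 2.51 ± 0.75 in polyA RNA (SD, n = 2 each), and fell by 2.18 after normexp (SE 0.26, adjusted p = 0.00038). The adjacent windows starting at 22410000 and 22415000 were among the brightest, at 3.71 ± 0.046 and 2.61 ± 0.012 in total RNA and 5.33 ± 1.2 and 4.41 ± 0.93 in polyA RNA (SD, n = 2 each). The former was lower by 1.15 in total RNA after normexp but higher by 0.122 after quantile normalization, so its direction depended on the scaling. The latter, and the windows starting at 24390000 and 44840000, differed by -1.68, -1.66 and -1.64 after normexp and by -0.467, -0.706 and -0.738 after quantile normalization. With both steps, the 5 runs lower in total RNA had mean differences between -0.836 and -0.762, so the sizes of these falls depended on the scaling too.

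The calls of this comparison depended on which arrays set the spread. As deposited, the SD between the MEFF polyA arrays reached 1.2 in bright windows, and with the MEFF polyA replicate 1 or 2 left out, 4485 and 3197 windows passed, because the spread then came from the total RNA pair alone. After normexp, the same 2 omissions gave 1283 and 1984 windows, and leaving out total RNA replicate 1 or 2 gave 172 and 81. With either total RNA array left out, 0 of the 5 runs higher in total RNA kept most of their windows called after normexp, although their differences stayed positive, between 0.669 and 1.02. The calls of these runs therefore need both total RNA arrays. Of the 5 runs lower in total RNA, 3 kept most of their windows without total RNA replicate 1, and 1, from 44800000 to 44844999, without replicate 2.

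The comparison of MEFB with MEFF polyA RNA set side by side 2 lines that keep opposite parental copies of the deleted interval. With intensities as deposited, 1 of 15383 windows passed limma's test, and 2415 passed at an unadjusted p of 0.05. After normexp, 488 passed, 302 higher and 186 lower in MEFB. After quantile normalization, 1047 passed (568 higher), after loess 382 (324 higher), and with a trended prior 405 (319 higher). MEFB had a single array, so no difference has a replicate check on that side, and line and parental copy cannot be separated.

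The clearest difference lay inside the deletion interval of the labels, where a run lower in MEFB stood beside a run higher in MEFB. From 12150000 to 12229999 (80 kb), the level as deposited was 2.07 and 2.03 in MEFF total RNA, 1.83 and 2.86 in MEFF polyA RNA, and 0.0554 in MEFB polyA RNA. The mean difference after normexp was -3.5, with 16 of 16 windows called (lowest adjusted p = 1e-08, limma). Among windows transcribed in MEFF or MEFB polyA RNA, the 5 with the largest fall in MEFB as deposited all lay in this run. Their differences lay between -2.69 and -2.52, with adjusted p between 0.11 and 0.15 (limma). The signal was continuous over the run rather than limited to single windows. From 12090000 to 12144999 (55 kb), MEFB stood at 1.27, against 0.161 and 0.364 in MEFF polyA RNA and 0.0342 and -0.0195 in MEFF total RNA. This run rose by 1.27 after normexp, with 10 of 11 windows called (lowest adjusted p = 0.0028). Further windows within the interval's numbers were called lower in MEFB at 12275000 to 12279999 (-1.43), 12345000 to 12369999 (-0.921) and 12650000 to 12659999 (-1.33), and single ones at 12675000 (-1.24) and 11525000 (-1.08). Single windows at 9625000 and 13160000 rose by 1.06 and 1.2.

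**Figure D3:**
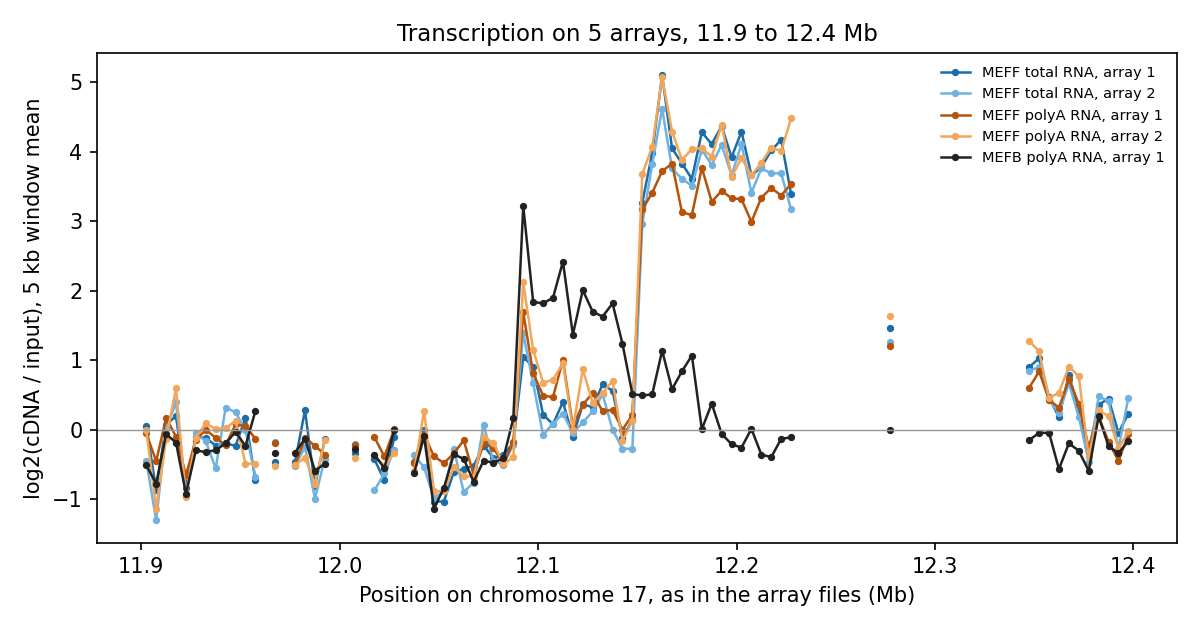
Level of each 5 kb window (y axis, log2(cDNA/input) after normexp) around the 2 neighbouring runs of the deletion interval (x axis, position as in the array files, Mb), 1 line per array, with gaps where windows lack probes. From 12150000 to 12229999 the 4 MEFF arrays averaged 3.39 to 4.06 and the MEFB array 0.222, while from 12090000 to 12144999 MEFB averaged 1.91 and the MEFF arrays 0.263 to 0.726.

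Counted over the whole interval from 8.6 to 13.2 Mb, 0 of 805 windows were called inside and 1 of 14578 outside as deposited, too few for a test. After normexp, 37 of 805 (4.6%) passed inside and 451 of 14578 (3.09%) outside (Fisher's exact test, p = 0.023), with 12 higher and 25 lower inside. Of these 37 calls, 26 belonged to the 2 adjoining runs, and 1.41% of the other 778 windows inside were called. The 1.41% leaves out the longest called runs, while the share outside keeps its own, so the 2 are not alike. At these numbers, most of the 37 calls came from 1 locus, whose neighbouring windows are not independent as the test takes them to be. After quantile normalization the shares were 7.08% and 6.79% (Fisher's exact test, p = 0.72), and after normexp without MEFF polyA replicate 1 they were 9.81% and 13.5%. The interval's numbers belong to another build than the probe positions. By the placing of probes described under processing, the 2 adjoining runs lay inside the deletion where they were placed, but so did the runs from 7935000 and 7980000, which the numbers leave outside. With the interval at placed positions, 40 of 842 windows (4.75%) passed inside after normexp and 3.08% outside (Fisher's exact test, p = 0.011). The runs from 7935000 and 7980000 held 6 and 8 of those calls, so the calls there were not those of 1 locus. The placed interval ended at file position 12199970, within the 80 kb run, and no later probe in the interval's file numbers was placed. The rest of that run and the called windows from 12275000 on were therefore counted as outside, although their side is open.

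Outside these numbers, the window from 77880000 to 77884999 was the single window called as deposited. It stood at 2.91 in MEFB against 0.144 ± 0.063 (SD, n = 2) in MEFF polyA RNA and -0.139 ± 0.06 (SD, n = 2) in MEFF total RNA, a rise of 2.77 (SE 0.1, adjusted p = 0.036, limma). The call was lost with a fit of the polyA groups alone and with either total RNA array left out (adjusted p = 0.13 each). Windows starting at 79950000, 78250000, 13535000 and 47630000 had differences of 2.44, 2.34, 2.09 and 1.96 as deposited (adjusted p of 0.066, 0.066, 0.066 and 0.11), and each passed after normexp at 2.92, 2.76, 2.58 and 2. The longest run higher in MEFB extended over 220 kb from 80000000 to 80219999, with 41 of 44 windows called. MEFB stood there at 0.675, while the 4 MEFF arrays lay between -0.248 and -0.085, and the run rose by 1.54 after normexp (lowest adjusted p = 5.4e-05). Runs from 62995000 to 63109999 (115 kb), 61135000 to 61224999 (90 kb) and 76745000 to 76824999 (80 kb) rose by 1.27, 1.12 and 1.14. Runs lower in MEFB were shorter and weaker than the one in the interval, at 7980000 to 8044999 (65 kb, -1.04), 70430000 to 70479999 (50 kb, -1.08), 7935000 to 7969999 (35 kb, -1.23) and 70120000 to 70154999 (35 kb, -1.27).

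The calls between the lines depended on it too. With MEFF polyA replicate 1 or 2 left out, 6984 and 6890 windows passed as deposited, and 2045 and 759 after normexp. With a total RNA array left out, 338 passed after normexp. The 2 runs side by side in the deletion interval and the runs from 80000000, 62995000 and 7935000 then kept most of their windows called, and those from 61135000, 76745000, 7980000, 70430000 and 70120000 did not.

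The genomic DNA channel was read as a check on the labels, since each line keeps 1 copy of the deleted interval. Over 22712 probes inside the interval, the median log2 input lay below that of the other probes by little on each array, with differences from -0.05 to -0.025. Their mean was -0.037 ± 0.011 (SD over 5 arrays). Of 172 equally long stretches along the chromosome, between 59 and 67 were as low on an array. These stretches overlapped each other, and some of them overlapped the interval. The input signal therefore did not show the deletion at these positions.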

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

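The combinations of normexp with another choice and the placed interval were chosen after seeing the data. No paired analysis was possible because replicate numbers were given only by order, and groups shared no labelled number. The 99th percentile of cDNA lay 5.33 to 22.4 times above the median, and the MEFF polyA arrays differed in it; whether this or the number of arrays limits the results more was not tested. Counts of transcribed windows stayed within 1.5 times of the main count under all alternatives run, but windows of other sizes are not like counts: the share in MEFF total RNA was 8.83% at 5 kb, 3.15% at 2 kb and 13.1% at 10 kb. Of 20 named windows under 14 alternatives fixed in advance, 181 values kept direction and side of the threshold, 89 passed where the main value did not, 6 lost the call and 2 changed direction. For the 20 named runs, 189 kept both, 91 newly passed and 0 changed direction. Of the 91, 20 were those of normexp, by whose calls the runs were chosen, so these 20 are no check. For the 46 named gene values, 347 kept both, 194 newly passed and 8 changed direction. Of the 194, 34 were those of normexp, by whose calls the genes outside the cluster list were chosen. The 6 lost calls were all of the window from 77880000, at adjusted p of 0.052 to 0.13. For windows of total minus polyA RNA (0 called), quantile normalization gave 929 calls, normexp 518 and both together 597. Leaving out 1 replicate gave 0 to 4485, and with normexp 172, 81, 1283 and 1984. For windows of MEFB minus MEFF (1 called), the median of probes gave 0, windows of 2 kb 4 and of 10 kb 10, loess 382, quantile normalization 1047, normexp 488, the cDNA channel alone 18, a trended prior 405, a fit of the polyA groups alone 0, and normexp with quantile normalization 973. Leaving out 1 replicate gave 0 to 6984, and with normexp 338, 338, 2045 and 759. With a MEFF polyA array left out, the spread comes from the total RNA pair alone, which by construction raises the counts where that pair is closer. With an array left out, the lone sample is assumed to vary like the other groups. For genes of total minus polyA RNA (0), loess gave 165, quantile normalization 323, normexp 342 and a trended prior 47, and leaving out 1 replicate 0 to 548. For genes of MEFB minus MEFF (0), the same settings gave 14, 146, 55 and 53, and leaving out 1 replicate 0 to 525. For introns (0), quantile normalization gave 70, normexp 9 and a trended prior 19, and leaving out 1 replicate 0 to 370. Gene lists passing in total minus polyA RNA fell from 9 to 0 with an estimated correlation. The percentage of called windows inside minus outside the interval, -0.00686 in the main setting, was 0.26 after loess, 0.29 after quantile normalization, 1.51 after normexp, 0.14 after both of the latter and 1.67 after normexp at placed positions. It was -15.3 and -11.2 without MEFF polyA replicate 1 or 2, no window passed without a total RNA array, and with normexp and 1 replicate left out 1.62, 1.62, -3.69 and 0.69. The input difference in the interval was -0.055 at placed positions after correction for sequence. The window from 22410000 changed direction after loess (0.601), quantile normalization (0.122) and normexp with quantile normalization (0.341). Gene values of total minus polyA RNA that changed direction, all uncalled, were those of Plg with the median of probes (0.0162), without dim probes (0.0166) and without MEFF total replicate 2 or MEFF polyA replicate 1 (0.0957, 0.114; -0.136 without replicate 2) and of Qk after quantile normalization (0.0989). For MEFB minus MEFF they were those of Map3k4 after quantile normalization (-0.149) and normexp (-0.37), both uncalled, and without MEFF polyA replicate 1 (-0.358, called; 0.57 without replicate 2, called). The window from 22415000 lost its normexp call after normexp with quantile normalization (-0.631). Apart from the cases named here by construction, the cause was not tested.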

Other observations

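The tests of background and range, missing DNA, Airn, Igf2r, genomic DNA, unspliced RNA and the build of the interval were chosen after the results were seen, as were the gene names given after normexp. Gene names are candidate identities, from probes placed on NCBIM37 by the input signal alone. Between the lines, 0 of 756 placed genes passed as deposited (limma, 68 at an unadjusted p of 0.05), and 55 passed after normexp, 22 higher and 33 lower in MEFB. Cdc42ep3, an effector of the GTPase Cdc42, rose by 3.56 (log2, SE 0.44, adjusted p = 5e-07), from 2.1 ± 0.018 (SD, n = 2) in MEFF polyA RNA to 5.66 in MEFB, and 9 of its 14 exon probes lie in the window called as deposited. Slc8a1, a sodium-calcium exchanger, rose by 3.28 (SE 0.44), and the run of 220 kb higher in MEFB lay over it, with 1220 of 1254 placed probes in the gene. Of the mesenchymal and matrix list, 3 of 14 tested members rose, namely Cyp1b1 (2.87), the laminin chain gene Lama1 (2.86) and Qpct (2.5), while Notch3 fell by 1.59. Adjusted over the list alone, 4 rose and 1 fell. Lbh (2.69), the choline transporter gene Slc5a7 (2.69), Clip4 (2.66), Ehd3 (2.45) and Rftn1 (2.22) also rose. After quantile normalization the rises were smaller, such as 2.72 for Cdc42ep3. They are least settled where MEFF lay near or below its array median, as for Lama1 (1.79 as deposited, 1.42 after quantile normalization), Slc5a7 (1.66, 1.33) and Qpct (1.87, 1.43). The falls below were larger after normexp than as deposited or after quantile normalization, and their sizes are not settled where MEFB lay near or below its array median. The largest fall was that of Msln, which encodes mesothelin, from 5.25 ± 0.5 (SD, n = 2) in MEFF polyA RNA to 0.137 in MEFB, a difference of -5.12 (SE 0.45, adjusted p = 1.4e-10), against -3.48 as deposited and -3 after quantile normalization. The transcription factor genes Nkx2-5 and Satb1 fell by 3.56 and 2.44, the lipid transporter gene Abcg1 by 3.12 and Angptl4, an inhibitor of lipoprotein lipase, by 2.78. As deposited, these differences were -1.84, -1.57, -1.91 and -1.64, and after quantile normalization -1.59, -1.36, -1.66 and -1.42. Rgs11 (-3.14), Sema6b (-3.12), Tpsab1 (-2.84), Kank3 (-2.77) and Pgp (-2.4) were lower too. For Pgp, the difference was -1.42 as deposited and -1.51 after quantile normalization. Pgp and Msln were also among the largest falls in total RNA. The 2 comparisons subtract the same MEFF polyA arrays, so for these genes the falls are not separate results. Of the Thp region and Igf2r cluster list, Igf2r rose by 2.13 (SE 0.45, adjusted p = 0.0011), and the other 10 tested gene models did not pass after normexp. After quantile normalization, Qk passed too (0.542, limma, adjusted p = 0.015), as did a gene model lower in MEFB. Further runs lower in MEFB lay in introns of Pde10a and Alk with 0 exon probes, while another lay over Fam179a with 42 exon probes in it. Runs higher in MEFB lay over Man2a1, Crim1 and introns of Efna5. The Efna5 run holds one called higher in total RNA, and both comparisons subtract the same 2 MEFF polyA arrays, so these are not separate results. Of 17 gene lists, 0 passed camera at the preset correlation, and the lowest adjusted p was 0.85 with an estimated correlation.

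Between MEFF total and polyA RNA, 0 of 756 genes passed as deposited (289 at an unadjusted p of 0.05), and 342 passed after normexp, 1 higher and 341 lower in total RNA, with a median difference over all genes of -0.782. Loess gave 165 and quantile normalization 323. The largest falls were in Pgp (3.61 against 6.63, -3.02), Mrpl28 (-2.8), Sepx1 (-2.59), Nme4 (-2.56) and Ddah2 (-2.53), each with an adjusted p of 6.8e-06 or below and an SE of 0.37 to 0.39. Mad2l1bp (-2.52), Ier3 (-2.51), Mrpl2 (-2.48), Msln (-2.23) and Nfkbil1 (-2.17) followed. After quantile normalization these 10 differences were smaller, from -1.6 for Mad2l1bp to -0.865 for Nfkbil1, with -1.57 for Pgp, so sizes and order depended on the scaling. Of the cell cycle and DNA repair list, 13 of 15 tested members fell, such as Chaf1a by 2.1 and Msh6 by 1.78, and adjusted over the list alone also 13. This list passed camera as deposited at the preset correlation (adjusted p = 0.014), with adjusted p = 0.72 with an estimated correlation. In all, 9 of 17 lists passed as deposited at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.44). Of the 9, only this list and the RNA processing list lay below the other genes. The lowest adjusted p of camera at the preset correlation were those of lists that lay above the other genes with few transcribed members. These were the olfactory and vomeronasal receptors (4.2e-08, 0 of 30 transcribed) and non-coding RNA (2.3e-05, 6 of 66). Passing therefore does not mark a pathway that falls. Of the RNA processing list, 7 of 11 members fell (8 adjusted over the list alone), of the stress and immediate early list 8 of 10 (also 8), and of the ribosomal protein and translation list 7 of 11 (also 7). Of markers of other cell types, 0 of 8 immune, 1 of 9 hepatic, 1 of 7 epithelial and 2 of 14 neural gene models were transcribed in MEFF, and 0 of 30 olfactory and vomeronasal receptor genes. Yet 2 of these receptor genes, below the array median in each group, were among those called lower in total RNA after normexp, so the 341 include genes with no signal. In introns, 0 of 609 genes passed as deposited (54 at an unadjusted p of 0.05), and after normexp Qk, which encodes an RNA-binding protein, was the single gene called higher in total RNA (0.921, SE 0.19, adjusted p = 0.047; MEFB polyA stood at 1.24, against 1.77 and 1.52 in total RNA and 0.626 and 0.817 in MEFF polyA RNA), with 8 lower, while quantile normalization gave 17 higher and 53 lower.

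Inside the deletion interval, the run of 80 kb lower in MEFB stood beside the run of 55 kb higher in MEFB. A difference of array background or range is argued against, since 0.9% of the other 111 windows at the same MEFF polyA level lay as far below it in MEFB. Missing DNA cannot be told apart by the MEFB input, which lay at -0.084 (log2) against MEFF over the run, because the input was not shown to follow copy number. Of 261 placed probes in the lower run, 257 lay in Airn, the paternally expressed non-coding RNA antisense to Igf2r. Of the same 261, 178 lay in Igf2r, 4 of them in its exons, and the cDNA keeps no strand. The run began in the window that holds the annotated start of Airn. Probes in Airn outside Igf2r differed by -3.7 (83 probes, SE over probes 0.17; -2.28 as deposited, -1.95 after quantile normalization) and exons of Igf2r, a maternally expressed gene, outside Airn by 2.13 (74 probes, SE 0.16; 2.64 over the 12 probes placed by the stricter rule). A candidate explanation is that MEFF keeps the paternal copy and MEFB the maternal one. This fits the usual order of writing Thp/+ with the maternal copy first. It does not account for the signal of these Igf2r exons in MEFF polyA RNA, at 2.58 and 3.09 after normexp against 4.96 in MEFB. Missing DNA and other differences between the lines stay open, with 1 MEFB array.

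Windows higher in total RNA held few exon probes. Of 98 placed windows called higher after normexp, 2.04% held an exon probe, against 92.6% of those called lower, and the longest runs lay in introns of Fbxl17, Lnpep, Zfand3 and Efna5. Exon-free transcribed windows lay above exon-holding ones of the same window mean by 0.778 in the median (0.499 as deposited, 0.456 after quantile normalization, 0.373 after loess). This argues against a compressed range of the total RNA arrays that acts on window means alone. Single probes were not matched, so a range effect on a few bright exon probes stays open. Genomic DNA left in total RNA cannot be judged from the place of these windows. Of them, 5.1% lay outside annotated genes, where 49.7% of all placed windows did. But centring on the array median removes a signal that is even along the chromosome, so it would not give windows called higher. The windows called lower had a similar share outside genes, 5.13%. Unspliced RNA kept in total RNA and lost by polyA selection cannot be told apart from something particular to the MEFF polyA arrays. For it, the intron difference lay above the exon difference in 98.6% of 296 transcribed genes (90.9% after quantile normalization, 89.5% after loess). Introns were themselves lower in total RNA in the median (-0.22, and -0.234 as deposited), and a range effect on the brighter exons would give the same sign, so this share alone does not separate the 2. Set against the MEFB polyA array instead, the share was 94.6% (80.1% after quantile normalization). Against it, the MEFB polyA array, which polyA selection would lower too, lay above MEFF polyA in 88.8% of the 98 windows, which were chosen for low MEFF polyA. The median of total RNA minus MEFB there was 0.328 after normexp and -0.109 as deposited. Array lot stays confounded with RNA type.

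The input signal showed no clear drop in the deletion interval. Numbers of another build could be the reason. At placed positions and after correction for sequence, at least 14.5% of equally long stretches were as low on every array. These stretches overlapped each other, and some overlapped the interval itself, so this share does not decide the question. The mean corrected difference was -0.055 ± 0.015 (SD over 5 arrays), where loss of 1 copy was estimated at -0.44 from the signal above the dimmest probes. Whether the amplified input follows copy number too weakly to show it cannot be told apart from other reasons, because the 14 probes off chromosome 17 have no known other copy number. No biological explanation was tested.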
